A study of Homo sapiens with 8464 samples.

How the data were processed

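Expression was measured by TempO-Seq on unpurified lysates of HepaRG cells in 384-well plates. The deposited matrix holds raw counts per probe, with a column for each well. The aligner, its version and the reference are not given in the sources used here, and the aim stated in the labels was 500 mapped reads per transcript. All columns were read, and they held whole numbers from 0 apart from 25 blank cells in wells without a labelled compound. Per the labels each compound was diluted into 10 concentrations from 500X stocks in DMSO, except PB and APAP, which were dissolved in medium, and the medium with compound was renewed after 48 h.

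Each column was matched to its sample by name, and the compound, concentration, culture state and replicate number were copied from the labels. The 3976 wells without a labelled compound (all 2208 of plate 4 and 104 of each other plate) were left out of the comparisons. The counts of the 3 wells of a compound and concentration on a plate, and of the 24 DMSO wells of a plate, were summed, because wells of a plate are technical replicates. For the contrast of culture states the DMSO sums of a replicate number were added up over plates, giving 3 against 3. The replicate number was taken as the run and n is the number of runs, 3, or 2 for plate 2 of proliferating cultures. No well was left out for low counts; 232 wells held under 10% of the median DMSO well of their plate.

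Tests used edgeR 4.0.16 in R 4.3.3 with TMM factors, filterByExpr (minimum count 10, minimum total 15), robust dispersions and the quasi-likelihood F test (glmQLFit, glmQLFTest). A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over the probes tested in that contrast. Each compound was fitted with its DMSO sums and all 10 concentrations of a state as separate groups, and the index concentration, the third highest, was compared with DMSO. The difference between states was tested as an interaction in a joint fit of both states. The pairs were compared directly at equal concentrations in a joint fit of both compounds. CPM are the normalised counts that edgeR's cpm gives with TMM library sizes after the filter, given as mean and SD over runs. The SE of a log2 change is its size divided by the square root of the quasi-likelihood F. Ratios against a group at 0 counts use a floor of 3 counts over the group with TMM library sizes, so they hold under that scaling.

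A set of 17 gene lists was written, and 16 of them had at least 5 probes measured and were tested with camera (limma 3.58.1, preset correlation 0.01) and again with an estimated correlation. The list of fatty acid synthesis had 3 probes and was not tested. The calls of list members are given over all probes tested and adjusted over the list alone. The lists, the index concentration, the tests, most alternatives and the rule for naming genes were set before the data were examined, while the list test between culture states was added later. The rule names the 12 probes with the largest rise and the 12 with the largest fall between states among called probes with at least 20 CPM in the higher group and no overlap between runs. For a compound it names the 5 largest rises and falls with the same direction in every run, for a pair 10 and for the interaction 3. It also allows members of the lists and a fixed set of target genes such as CYP1A1, CYP3A4, PLIN2 and GDF15 for any compound and concentration. Fewer may be named, the largest first, and some genes that the rule allows are not given. The target genes NR0B2, FGF19, PDK4, ANGPTL4 and ASNS were not on the panel.

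The lowest active concentration was compared between states by a two-sided permutation test over compounds (sign flips, 100000 resamples). A compound that was active at no concentration in a state was set at 1 dilution step above its top concentration.

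Whether replicate numbers pair the samples was checked from correlations across probes of the residuals of treated and DMSO sums. The correlation of a treated sum with the DMSO of its own plate had a median of 0.614 in differentiated (72 pairs, 0.247 to 0.824) and 0.554 in proliferating cultures (64 pairs, 0.172 to 0.794), and 71 and 62 of these were highest with their own plate. On plate 2 of proliferating cultures, with 2 runs, the correlations with the own and the other plate mirrored each other (0.526 and -0.526 for CPZ). Between states the correlations of equal numbers were 0.895, 0.597 and 0.612, and the highest with another number -0.680, 0.555 and 0.470. The numbers thus pair the samples within a state, while between states replicate 1 alone stood clearly apart. Values with the replicate number as a block are given beside the results they change.

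The tests were tested on simulated data with the mean of each probe in DMSO, the real depths and the fitted spread, and with 200 changed genes in each set. Each simulated sum was drawn independently, so the correlation of sums that share a replicate number was not in these data. The culture state adds up such independent plate sums, so its recovered share may be too high. At a change of 4-fold 77.3% were recovered for a compound on differentiated plate 1, 90.9% on differentiated plate 2, 95.5% on proliferating plate 1 and 77.3% on proliferating plate 2 with n = 2. It was 100% for the culture state, 69.7% and 50% for the interaction on plates 1 and 2, and 69.7% for a pair. At 2-fold the recovered share was 22.4%, 41.8%, 71.6% and 19.4% for the compound fits in that order, 91% for the culture state, 17.9% and 1.49% for the interaction and 22.4% for a pair. Between 1 and 7 unchanged genes were called in each set, and the pass marks of this check were set after a first run.

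The alternatives were DESeq2 1.42.0, RLE factors in edgeR, no filter, the replicate block, each replicate left out, wells with low counts left out, DMSO wells of column 23 alone, plates as samples and the groups of the contrast alone. Others were the lowest concentration as the reference, replicates 1 and 3 alone for plate 2, at least 20 probes for an active concentration, and an estimated correlation for lists. Leaving out compounds with low depth and leaving out PB and APAP were added after seeing the data. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and figures with matplotlib 3.10.9.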

Results

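HepaRG is an established human liver progenitor cell line that can mature into hepatocyte-like and biliary-like cells. Its expression was measured by TempO-Seq, in which pairs of short detector probes are joined on their target RNA in a crude lysate and the joined products are counted by sequencing. The panel held 2977 probes for 2733 genes, and the positions of the probes on the genome were not given in the sources used here. Differentiated cultures were seeded at 20000 cells per well 10 days before exposure and proliferating, undifferentiated cultures at 2000 cells per well 3 days before, so cell density and time in culture changed together with the state. Both states were exposed for 96 h to DMSO or to 1 of 24 compounds at 10 concentrations. The compounds were spread over 3 plate layouts with 8 compounds each, and each layout was run 3 times. The labels number these runs but do not say whether they were separate thaws, so the p-values measure the spread between these runs. The proliferating plate 2 of replicate 2 was not analysed here, which left n = 2 runs for its 8 compounds.

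The count table held 4488 wells with labels and 3976 without. The labelled ones were 2376 differentiated wells with 216 DMSO wells among them, and 2112 proliferating wells with 192 DMSO wells. A labelled well held between 114 and 4796621 counts, with a median of 1025764. The 3 wells of each concentration on a plate were summed, as were its 24 DMSO wells. These sums ranged from 4343 to 39812465 counts with a median of 3143541, and the DMSO sums of a plate from 22455478 to 39812465. The 10 most abundant probes took 13.5% of all counts, and the most abundant, MT-ND6, took 2.43%. Counts fell at the highest concentrations of several compounds: at the top concentration troglitazone left 0.400% of the DMSO counts per well in differentiated and 0.224% in proliferating cultures, and aflatoxin 0.869% and 0.187%. Floors rest on counting alone, and reads without molecular identifiers are not independent molecules.

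**Figure D1:**
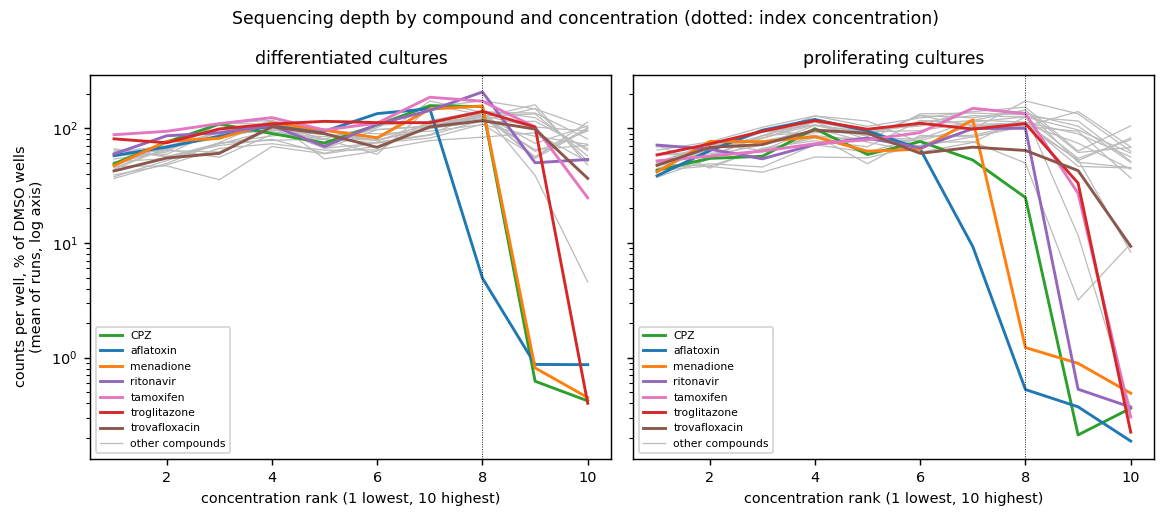
Mean counts per well as a percent of the DMSO wells on the same plates (log axis) against concentration rank, 1 lowest and 10 highest, for each compound in differentiated (left) and proliferating (right) cultures, each line the mean of the runs. At the index concentration (dotted) aflatoxin held 4.94% in differentiated and 0.528% in proliferating cultures, and menadione 156% and 1.23%.

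The first comparison asked how the 2 culture states differed in the DMSO wells, after 96 h without a compound. Among the genes higher in differentiated cultures were CRP and HP, which encode plasma proteins made by hepatocytes. CRP, of the acute phase, was at 22.7 ± 3.59 CPM against 0.712 ± 0.25 CPM in proliferating cultures (SD, n = 3 runs each). HP, the haemoglobin carrier haptoglobin, was at 1362 ± 231 against 340 ± 108 CPM, with the limit that its probe was not checked against the paralog HPR. CA9, a carbonic anhydrase induced by low oxygen, was higher as well, at 401 ± 63.9 against 28.2 ± 6.47 CPM. Proliferating cultures had more CYP1A1, a target of the aryl hydrocarbon receptor (AHR), at 57.9 ± 11.5 against 3.61 ± 0.551 CPM, and more NQO1, a target of the oxidant-sensing factor NRF2, at 240 ± 22.2 against 58.8 ± 5.83 CPM. MKI67, a marker of dividing cells, was at 80.1 ± 11.6 CPM in proliferating and 38.4 ± 5.17 CPM in differentiated cultures.

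On the log2 scale, differentiated minus proliferating, the differences were 5.01 ± 0.31 (SE) for CRP (adjusted p = 0.000134), 2.00 ± 0.24 for HP, and 3.83 ± 0.22 for CA9 (adjusted p = 9.8e-05). They were -4.0 ± 0.21 for CYP1A1 (adjusted p = 9.2e-05) and -2.03 ± 0.13 for the more abundant of 2 NQO1 probes (adjusted p = 0.000134). MKI67 differed by -1.06 ± 0.16 (adjusted p = 0.0048), a call lost without replicate 2 (adjusted p = 0.0822) or without replicate 3 (0.0731). Among probes of at least 20 CPM the largest difference was that of CD3D, a T-cell receptor subunit, at 59.1 ± 10.7 against 1.46 ± 0.0161 CPM (5.34 ± 0.18 on the log2 scale, adjusted p = 1.8e-05). SLC51A, a bile acid exporter, followed CD3D and TREM1 with 5.06 ± 0.90 (adjusted p = 0.014; 0.0906 without replicate 2 and 0.119 without replicate 3). FABP4, a lipid carrier, was higher in differentiated cultures by 2.49 ± 0.19, and so was CYP3A4, the main drug-oxidising enzyme of adult liver, by 1.72 ± 0.26 (adjusted p = 0.0053, and 0.114 without replicate 3). The sulfotransferase SULT2A1 was higher in proliferating cultures (-2.09 ± 0.42, adjusted p = 0.016; 0.144 without replicate 2 and 0.11 without replicate 3).

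Of 2831 probes tested, 412 for 386 genes were called, 245 higher in differentiated and 167 higher in proliferating cultures. All 412 had values that did not overlap between states, which chance gives 10% of unselected probes. These probes were selected by a test on the same values, so the lack of overlap is no separate support. A total of 790 passed an unadjusted p of 0.05. With the replicate number as a block the count was 948, and it was 79 without replicate 2 and 106 without replicate 3. Among the gene lists fixed before the data were examined, the cell cycle list was lower in differentiated cultures (0 up and 15 down of 35 probes, or 0 and 23 adjusted over the list alone; adjusted p = 9e-11, and 0.191 with an estimated correlation). The NRF2 list was lower too, with 0 up and 8 down of 19 (1 and 12 adjusted over the list alone; adjusted p = 2.9e-07, 0.0654 with an estimated correlation), as was the AHR list, with 0 up and 3 down of 10 both ways (0.000106, 0.0940). The hepatocyte list was higher, with 9 up and 1 down of 16 (11 and 1 adjusted over the list alone; adjusted p = 6.4e-09, 0.191 with an estimated correlation). So were the inflammation list, with 7 up and 1 down of 19 (9 and 2; 0.00195, 0.191), and the unfolded protein response list, with 6 up and 0 down of 19 (8 and 0; 0.00653, 0.191). The heat shock and metal list (5 up and 1 down of 17) had an adjusted p of 0.0267, which became 0.191 with an estimated correlation, 0.0606 without replicate 2 and 0.0809 without replicate 3. The bile acid receptor (FXR) list (2 up and 0 down of 8, 3 and 0 adjusted over the list alone) had 0.0385, which became 0.304 with an estimated correlation and 0.0809 without replicate 3.

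The other 8 lists were not called between states. Their adjusted p was 0.777 for the list of the nuclear receptors PXR and CAR (5 up and 6 down of 20) and for cholesterol synthesis (0 and 0 of 13), 0.474 for macrophage genes (2 and 0 of 7). It was 0.384 for p53 targets (0 and 0 of 25) and 0.224 for PPAR targets (4 and 2 of 13) and endothelial genes (2 and 0 of 5). The PXR and CAR test pointed lower in differentiated cultures although the median difference was 0.0868 and the mean 0.348, and the endothelial list had a median of -0.0709 and a mean of 0.434. Biliary genes (3 up and 1 down of 7) had an adjusted p of 0.114, which became 0.0117 with the block and 0.0122 without replicate 1. Mesenchymal genes (5 up and 2 down of 20) had 0.224, which became 0.0480 with the block and 0.0254 without replicate 3.

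**Figure D2:**
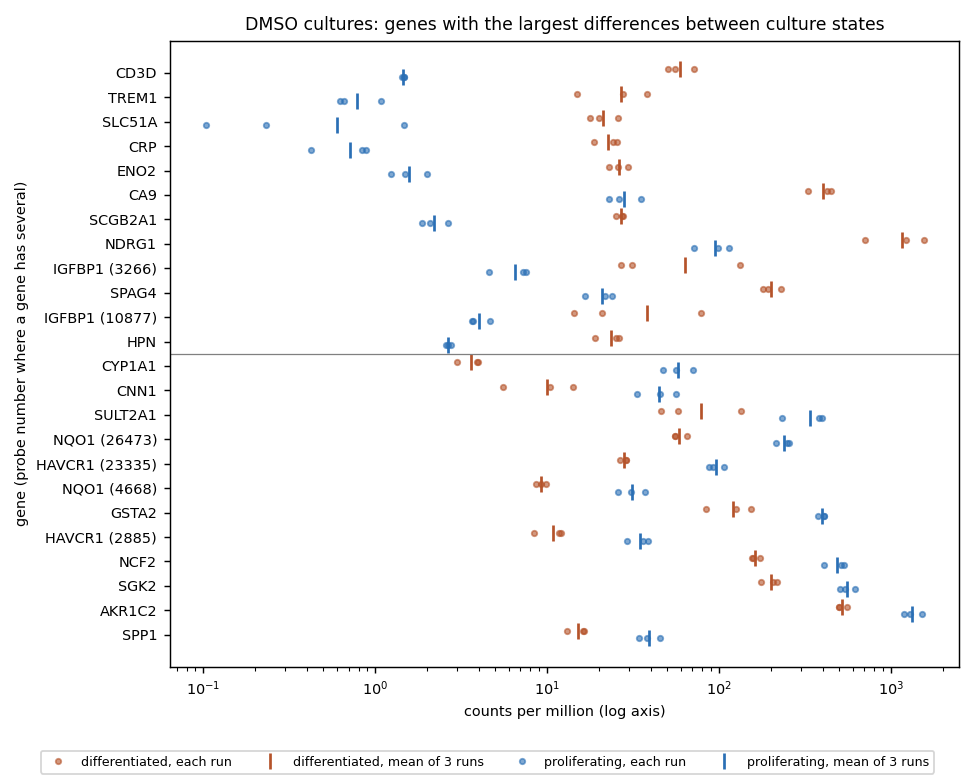
CPM (log axis) of the 12 probes with the largest difference in each direction between DMSO cultures, with a point per run and a bar at the mean of 3 runs. In every probe shown the runs of one state lie apart from those of the other, from CD3D at 59.1 against 1.46 CPM to SPP1 at 15.2 against 39.2 CPM.

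The next comparisons asked which transcripts each compound changed against DMSO at its index concentration, the third highest of 10. In differentiated cultures 4542 probe changes were called over the 24 compounds, 2371 higher and 2171 lower, and in proliferating cultures 5737, of which 2866 were higher and 2871 lower. Aflatoxin changed the most probes in both states with all runs (1405 and 1565), followed in differentiated cultures by the polycyclic hydrocarbon B[a]P (1039), the fluoroquinolone trovafloxacin (734), the protease inhibitor ritonavir (542), the quinone menadione (319), the analgesic APAP (acetaminophen, 279) and CPZ (108). In proliferating cultures the counts were 1137 for B[a]P, 877 for trovafloxacin, 790 for APAP, 774 for menadione, 249 for troglitazone, 187 for rosiglitazone, 71 for ritonavir and 62 for CPZ. With DESeq2 the counts in proliferating cultures were 1203 for menadione, 499 for CPZ and 263 for ritonavir, and they were 168, 0 and 28 when the groups of the contrast were fitted alone. Without wells of low counts they were 327 for CPZ and 194 for ritonavir, and with the lowest concentration as the reference 124 for CPZ and 44 for rosiglitazone. In differentiated cultures DESeq2 gave 536 for menadione and 361 for CPZ, the fit without wells of low counts 529 and 321, and the groups alone 481 and 0. In differentiated cultures rosiglitazone changed 61 probes, troglitazone 33 and OMP 10, and in proliferating cultures OMP changed 19. With DESeq2 these were 122, 76, 25 and 62, with the groups alone 18, 12, 7 and 8, and with the lowest concentration as the reference 9, 14, 6 and 26. With the replicate number as a block the totals were 8686 and 9270, and the number of compounds with at least 10 calls rose from 10 in each state to 19 in differentiated and 16 in proliferating cultures.

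Counts depended on single runs. In differentiated cultures the count without replicate 1 was 296 for ritonavir, 65 for CPZ, 52 for troglitazone and 1 for OMP. Without replicate 2 it was 750 for aflatoxin, below the 787 for B[a]P, 375 for trovafloxacin, 338 for ritonavir, 149 for menadione, 106 for APAP, 25 for rosiglitazone, 2 for CPZ and 2 for troglitazone, and the OMP calls were lost. Without replicate 3 it was 871 for aflatoxin, 661 for B[a]P, 360 for ritonavir, 140 for APAP, 12 for rosiglitazone and 5 for troglitazone, and the CPZ calls were lost. In proliferating cultures it was 892 for aflatoxin, below the 961 for B[a]P, 116 for rosiglitazone and 1 for OMP without replicate 1. Without replicate 2 it was 717 for B[a]P, 517 for trovafloxacin, 455 for APAP, 100 for troglitazone, 73 for rosiglitazone and 1 for OMP, and without replicate 3 it was 512 for APAP and 111 for troglitazone. With the groups of the contrast alone aflatoxin was below B[a]P there as well (959 and 1311), so which of them changed more probes was not settled.

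The split into higher and lower probes depended on the scaling for the compounds that changed the most. In proliferating cultures 50.0% of calls were higher with TMM, 67.2% with RLE and 67.7% with DESeq2. The median of all probes moved by 1.14 on the log2 scale between TMM and RLE for aflatoxin, by 1.44 for menadione, by 0.565 for CPZ and by 0.155 for APAP in these cultures, and in differentiated cultures by 0.457 for aflatoxin and 0.141 for CPZ. Changes of these compounds are therefore relative to a scaling that the data do not fix to better than these shifts.

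**Figure D3:**
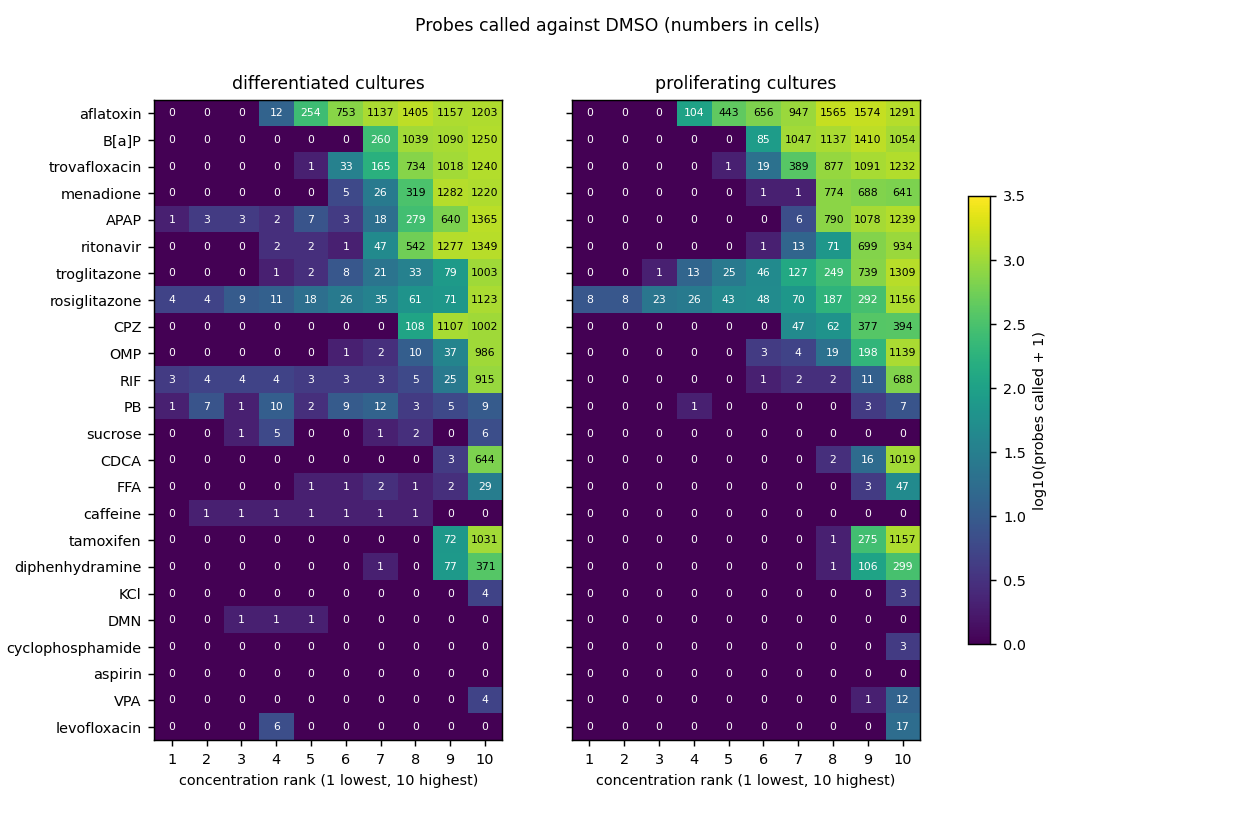
Number of probes called against DMSO for each compound (vertical) and concentration rank (horizontal) in both states, with the number in each cell and its colour on a log scale. Rosiglitazone had calls at every rank, from 4 to 1123 in differentiated and from 8 to 1156 in proliferating cultures, while edgeR without the block called none for aspirin at any rank in either state.

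The thiazolidinediones rosiglitazone and troglitazone raised genes of fat storage, the targets of the nuclear receptor PPARG. FABP4 went from 280 ± 53.7 to 24785 ± 4362 CPM (SD, n = 3 runs each) with rosiglitazone in differentiated cultures and from 51.2 ± 18.2 to 21315 ± 5806 CPM in proliferating cultures. PLIN2, which coats lipid droplets, went from 833 ± 382 to 5264 ± 1103 CPM and from 402 ± 35.1 to 2815 ± 416 CPM. Both drugs also raised CYP3A4, a target of PXR, measured by the more abundant of its 2 probes, for which its paralogs CYP3A5 and CYP3A7 are not ruled out as a source of signal. With rosiglitazone it went from 114 ± 58.9 to 3875 ± 1737 CPM in differentiated and from 33 ± 8.58 to 1868 ± 1322 CPM in proliferating cultures.

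On the log2 scale FABP4 rose by 6.47 ± 0.56 (SE; adjusted p = 1.5e-08) with rosiglitazone and 6.71 ± 0.79 (adjusted p = 1e-05) with troglitazone in differentiated cultures, and by 8.70 ± 0.68 and 8.64 ± 1.06 in proliferating cultures. CYP3A4 rose by 5.09 ± 0.91 (adjusted p = 0.0015) with rosiglitazone and by 4.37 ± 0.64 with troglitazone (adjusted p = 0.00011, and 0.128 without replicate 2) in differentiated cultures, and by 5.82 ± 0.50 and 4.31 ± 0.35 in proliferating cultures. ADIPOQ, a hormone of fat cells, rose from 1.53 ± 1.08 to 14.9 ± 4.63 CPM with rosiglitazone in proliferating cultures (3.25 ± 0.50 on the log2 scale, adjusted p = 6e-05). In differentiated cultures its rise of 2.90 ± 0.64 (adjusted p = 0.0089) was not called without replicate 2 (0.221) or without replicate 3 (0.469) and was 4.36 without replicate 1. ADIPOQ there was no higher than at the lowest rosiglitazone concentration. PLIN2 was called at every rosiglitazone concentration in both states, from 1.54 at 0.00949 µM to 4.14 at 300 µM in differentiated cultures and from 1.17 to 4.76 in proliferating cultures. FFA raised PLIN2 at its top concentration of 300 µM by 2.82 ± 0.46 (adjusted p = 0.001; 0.0756 without replicate 1 and 0.0858 without replicate 3) in differentiated and by 2.79 ± 0.28 in proliferating cultures.

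The PPAR list was higher with rosiglitazone in differentiated cultures (5 up and 0 down of 14 probes, 10 and 0 adjusted over the list alone, adjusted p = 4.9e-05 with an estimated correlation) and in proliferating cultures (12 and 0 of 14, 14 and 0; 0.00191). The same list was higher with troglitazone (4 and 0 of 13, 5 and 0, with 0.000257, and 10 and 0 of 14, 13 and 0, with 0.01). The PXR and CAR list was higher with both drugs in proliferating cultures (12 and 0 of 19 with rosiglitazone, 8 and 0 of 19 with troglitazone; adjusted p = 0.000673 and 0.0023 with an estimated correlation). In differentiated cultures its calls (4 and 0 of 19, and 4 and 0 of 20) did not hold with an estimated correlation (adjusted p = 0.194 and 0.179). The cell cycle list was called lower with rosiglitazone with the preset correlation alone (0 and 2 of 32 in differentiated, 0 and 7 of 33 in proliferating cultures; adjusted p = 8.29e-12 and 1.05e-08, 0.143 and 0.24 with an estimated correlation). Troglitazone lowered FGG, a fibrinogen chain made by hepatocytes, in proliferating cultures from 779 ± 143 to 155 ± 71.2 CPM (-2.33 ± 0.26 on the log2 scale). The inflammation and acute-phase list was lower there as well, with 1 up and 6 down of 17 (adjusted p = 0.0412 with an estimated correlation).

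RIF raised CYP3A4 and CYP3A5, the drug-oxidising enzymes under PXR, and few other genes. In differentiated cultures CYP3A4 went from 103 ± 24 to 8200 ± 1398 CPM (SD, n = 3), a rise of 6.31 ± 0.49 on the log2 scale (adjusted p = 9.2e-10), and CYP3A5 from 174 ± 30.1 to 3603 ± 260 CPM, by 4.37 ± 0.32. CYP3A4 was called at the lowest RIF concentration, 0.0092 µM, with 3.20 ± 0.42 (adjusted p = 6.9e-05; 0.30 without replicate 1 and 0.505 without replicate 2), rose to 6.32 at 92.02 µM and was at 0.68 and not called at 291 µM. In proliferating cultures (n = 2) CYP3A4 rose by 4.57 ± 0.66 (adjusted p = 0.012), to 640 ± 255 CPM, and was called from 2.91 µM. A total of 5 probes were called with RIF in differentiated cultures and 2 in proliferating cultures (46 and 5 with the block), and the first count was 3 without replicate 2 and 3 without replicate 3. The PXR and CAR list was higher in both states (5 and 0 of 19, and 2 and 0 of 18; adjusted p = 5e-06 and 0.000794 with an estimated correlation).

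PB (phenobarbital), an activator of CAR, raised CYP3A4 only at its highest concentrations. In differentiated cultures CYP3A4 rose by 4.66 at 316.2 µM and by 6.28 ± 0.54 (adjusted p = 4.8e-09) at 1000 µM, where it reached 4945 ± 1096 CPM (n = 3), and in proliferating cultures by 3.72 and 5.65 ± 0.44. CYP2B6, the classical CAR target, rose in differentiated cultures at 1000 µM from 6.84 ± 4.49 to 49 ± 24.1 CPM (2.83 ± 0.64, adjusted p = 0.035; 0.761 without replicate 1 and 0.20 without replicate 2). PB and APAP were dissolved in medium per the labels while their controls held DMSO, so their differences include that of the vehicle: at the index concentration of 100 µM, 3 probes were called with PB in differentiated cultures (283 with the block, 21 with DESeq2), S100A2, FABP4 and ALDH2, and none of these calls held with any replicate left out. The concentrations below it gave between 1 and 12 calls.

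**Figure D4:**
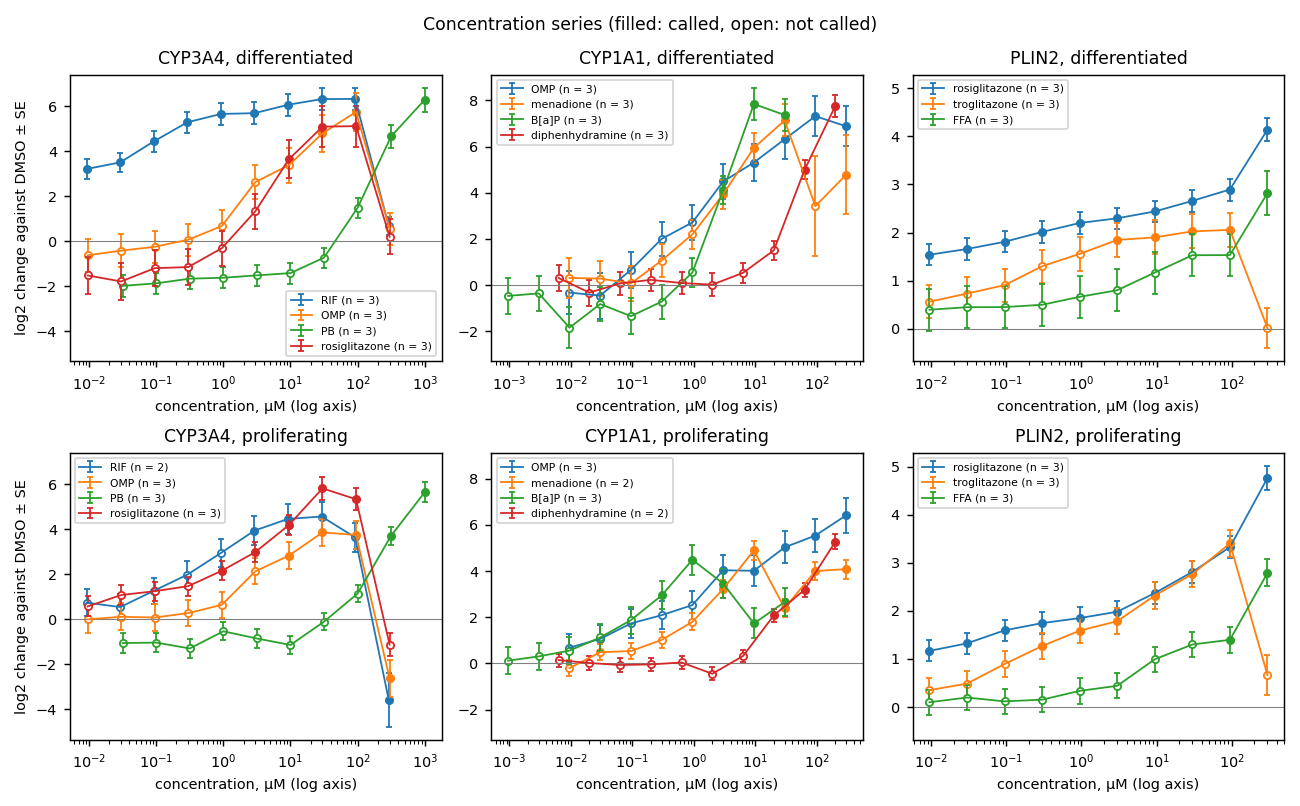
Log2 change against DMSO with its SE at each concentration (µM, log axis) for CYP3A4, CYP1A1 and PLIN2 in differentiated (top) and proliferating (bottom) cultures, filled points called and open points not. With RIF, CYP3A4 was called at 9 of 10 concentrations in differentiated cultures and from 2.91 µM in proliferating cultures, and CYP1A1 reached 7.84 with B[a]P at 9.487 µM.

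CYP1A1, a target of AHR, rose with compounds of unlike structure, and CYP1B1, another target, with some of these. Menadione raised CYP1A1 in differentiated cultures from 2.96 ± 0.951 to 416 ± 115 CPM (n = 3; 7.13 ± 0.70 on the log2 scale, adjusted p = 3.9e-08) and CYP1B1 from 24.1 ± 4.32 to 372 ± 134 CPM (3.94 ± 0.35). OMP raised CYP1A1 from 3.24 ± 0.444 to 260 ± 119 CPM (6.32 ± 0.84, adjusted p = 6e-05; 0.0776 without replicate 1 and 0.23 without replicate 2). In proliferating cultures OMP raised CYP1A1 from 53 ± 9.18 to 1728 ± 445 CPM (5.03 ± 0.70, adjusted p = 0.00024; 0.435 without replicate 1 and 0.0749 without replicate 2). B[a]P, the classical ligand of AHR, raised CYP1A1 by 4.11 ± 0.61 at 3 µM and by 7.84 ± 0.71 at 9.487 µM in differentiated cultures, and in proliferating cultures by 2.95 ± 0.60 at 0.3 µM and at most by 4.49 at 0.9487 µM. Diphenhydramine raised CYP1A1 at 200 µM from 2.82 ± 0.936 to 609 ± 50.5 CPM in differentiated cultures (7.76 ± 0.46) and by 2.08 ± 0.29 at 20 µM in proliferating cultures (n = 2, adjusted p = 0.0087). Trovafloxacin raised CYP1A1 in differentiated cultures from 3.47 ± 0.462 to 43.2 ± 16.7 CPM (3.63 ± 0.53, adjusted p = 6.3e-06). With CPZ at 94.88 µM the rise of 6.08 ± 0.74 rested on 23 counts.

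The AHR list was higher with OMP in both states (2 up and 0 down of 9 probes, and 3 and 0 of 8; adjusted p = 0.000354 and 0.00813 with an estimated correlation). It was also higher with menadione in differentiated cultures (6 and 0 of 7; 0.000107) and with diphenhydramine in proliferating cultures (1 and 0 of 8; 0.00112). OMP also raised CYP3A4, from 63.4 ± 25.8 to 1752 ± 767 CPM in differentiated cultures (4.79 ± 0.82, adjusted p = 0.0023; 0.108 without replicate 1 and 0.418 without replicate 2) and by 3.87 ± 0.62 in proliferating cultures (0.455 without replicate 1 and 0.0522 without replicate 2).

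Menadione lowered transcripts of hepatocyte genes in differentiated cultures and raised those of cell cycle genes. CYP3A4 fell from 111 ± 26.9 to 3.55 ± 0.104 CPM (-4.95 ± 0.36 on the log2 scale, adjusted p = 7.2e-13, n = 3). CYP2C8, another drug-oxidising enzyme, fell from 1063 ± 262 to 83.1 ± 9.51 CPM (-3.68 ± 0.36), and the bile acid transporters SLC51A and SLCO1B1 changed by -3.28 ± 0.37 and -2.71 ± 0.26. HSPA6, a heat shock protein made only under stress, rose from 0.429 ± 0.322 to 94.7 ± 60 CPM (7.73 ± 0.79), NQO1 by 1.6 ± 0.30 (adjusted p = 0.00015) and HMOX1, which degrades haem, by 1.09 ± 0.29 (adjusted p = 0.0093, 0.144 without replicate 2). The kinase PLK1 and the thymidine kinase TK1, which dividing cells make, rose by 2.18 ± 0.41 and 1.93 ± 0.28.

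With menadione in differentiated cultures the hepatocyte list had 0 up and 13 down of 16 probes (0 and 14 adjusted over the list alone; adjusted p = 0.000107 with an estimated correlation), and the FXR list 0 and 4 of 6 (0 and 5; 0.000223). The PXR and CAR list had 0 and 9 of 19 (2 and 9; 0.000374), and the cell cycle list 20 and 0 of 34 (24 and 0; 0.00164). The NRF2 list, with 4 up and 1 down of 18 (7 and 1), had an adjusted p of 0.0113 with the preset and 0.447 with an estimated correlation. In proliferating cultures (n = 2) menadione at the same concentration left 1.23% of the DMSO counts. HSPA6 rose there from 0.793 ± 0.0359 to 1063 ± 1479 CPM on 91 counts, and F2, the clotting factor prothrombin, was at 0 counts, at least 7.72-fold lower by a floor of 3 counts over the group with TMM. RLE moved the median of all probes there by 1.44 on the log2 scale, so this bound depends on the scaling.

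The metabolites of aflatoxin and B[a]P bind DNA. In CPM, aflatoxin in differentiated cultures and B[a]P in both states raised single targets of p53 and genes of the cell cycle. No call of these lists held with an estimated correlation. GDF15, a secreted stress hormone, went from 743 ± 544 to 11694 ± 3828 CPM with aflatoxin in differentiated cultures (3.98 ± 0.44 on the log2 scale, adjusted p = 9.3e-09, n = 3). GADD45A, a p53 target that halts division, went from 203 ± 31.1 to 1330 ± 429 CPM (2.71 ± 0.30). MKI67 went from 42.6 ± 9.49 to 868 ± 317 CPM (4.35 ± 0.36), while ALB, the plasma protein albumin, went from 14940 ± 3317 to 699 ± 207 CPM (-4.42 ± 0.37). The treated wells held 4.94% of the DMSO counts per well, so these CPM are shares of the counts left. They do not show a rise per well. The 3 treated sums held 156361, 178450 and 162243 counts, and HNF4A, a transcription factor of hepatocytes, was at 0 counts in all 3, at least 5.89-fold lower with TMM. In proliferating cultures the treated sums held 33834, 19576 and 17199 counts. CYP3A5 was at 0 counts there, at least 7.66-fold lower than its 282 ± 18.2 CPM in DMSO with TMM, while RLE moved the median of all probes by 1.14 on the log2 scale. Counts of probes near 0 in DMSO did not fall with the total in these sums, so rises of the rarest transcripts there are not separable from a background of counts in each well. MCEMP1, which rose from 1.20 ± 0.386 to 107 ± 12.9 CPM in differentiated cultures, had 72 counts in 9 treated wells and 101 in 72 DMSO wells, which is more per treated well.

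B[a]P raised DDB2, a DNA repair gene under p53, in differentiated cultures from 166 ± 7.85 to 642 ± 88 CPM (1.95 ± 0.14 on the log2 scale, adjusted p = 7.7e-11, n = 3). It raised the p53 target BTG2 by 2.02 ± 0.37 and the mitotic kinase CDK1 from 111 ± 9.57 to 869 ± 52.2 CPM (2.97 ± 0.27). In proliferating cultures it raised AREG, a growth factor of the EGF family, from 32.1 ± 1.51 to 1585 ± 161 CPM (5.62 ± 0.45), GDF15 by 3.42 ± 0.39 and GADD45A by 2.16 ± 0.25. MSMO1, of cholesterol synthesis, fell there from 3626 ± 217 to 452 ± 214 CPM (-3.01 ± 0.32).

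With B[a]P the p53 list had 16 up and 2 down of 25 probes in differentiated cultures (adjusted p = 4.86e-05, 0.113 with an estimated correlation) and 19 and 0 in proliferating cultures (21 and 0 adjusted over the list alone; 9.48e-08, 0.0704). The cell cycle list had 24 and 2 of 33 (26 and 2; 3.81e-10, 0.179) and 22 and 0 of 35 (5.71e-07, 0.0858). Cholesterol synthesis had 0 and 12 of 13 in proliferating cultures (0.000134, 0.134), and the hepatocyte list 0 and 15 of 16 (1.88e-12, 0.134). With aflatoxin in differentiated cultures the cell cycle list had 28 up and 0 down of 35 (adjusted p = 3.7e-10, 0.0574 with an estimated correlation) and the hepatocyte list 0 and 14 of 16 (1.89e-09, 0.147). The p53 list had 10 and 1 of 25 (0.0217, 0.412 with an estimated correlation, 0.0633 without replicate 2 and 0.0847 without replicate 3).

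Trovafloxacin raised single p53 targets and lowered single genes of cholesterol synthesis and of the cell matrix, while no call of these lists held with an estimated correlation in either state. GDF15 went from 873 ± 629 to 7327 ± 61.3 CPM in differentiated cultures (3.07 ± 0.55 on the log2 scale, adjusted p = 0.00011, n = 3) and reached 26819 ± 3034 CPM at 300 µM. In proliferating cultures GDF15 went from 1227 ± 778 to 8888 ± 1398 CPM (2.86 ± 0.62, adjusted p = 0.0009, 0.0855 without replicate 2). GADD45A rose by 2.00 ± 0.34 and 2.45 ± 0.27, and the more abundant probe of TNFRSF10B, a death receptor under p53, by 2.44 ± 0.19 in proliferating cultures. INSIG1, which is made when sterols are low, fell from 1155 ± 409 to 268 ± 122 CPM (-2.11 ± 0.37) and from 662 ± 170 to 110 ± 33 CPM (-2.59 ± 0.40). The collagen gene COL3A1 was lower in differentiated cultures (-2.41 ± 0.50) and CNN1, of contractile cells, in proliferating cultures (-4.16 ± 0.67). The p53 list had 14 up and 2 down of 25 probes and 15 and 3 (adjusted p = 0.000838 and 3.13e-07, 0.196 and 0.134 with an estimated correlation). The cell cycle list had 19 and 0 of 33 and 15 and 0 of 34 (3.47e-07 and 0.00014, 0.344 and 0.385 with an estimated correlation). Cholesterol synthesis had 0 and 8 of 13 in both (0.00133 and 9.74e-05, 0.179 and 0.0704 with an estimated correlation). The mesenchymal and matrix list had 1 and 8 of 18 and 2 and 8 (0.0168 and 0.0302, 0.123 and 0.134 with an estimated correlation, and 0.0669 without replicate 1 in proliferating cultures).

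APAP at 2000 µM raised cell cycle genes and, in proliferating cultures, lowered drug-metabolising genes under PXR and CAR, both with the difference of vehicle given for PB. With the lowest APAP concentration as the reference, 204 probes were called in differentiated and 815 in proliferating cultures (279 and 790 against DMSO). Counts of this size thus did not rest on the DMSO reference alone. TK1 rose from 31.5 ± 9.31 to 151 ± 26.6 CPM in differentiated cultures (2.26 ± 0.26 on the log2 scale, adjusted p = 1.8e-06, n = 3), and CDC6, which starts replication, from 23 ± 3.89 to 98.5 ± 18 CPM (2.10 ± 0.28). CYP2B6 rose there from 7.18 ± 4.77 to 39.7 ± 29.1 CPM (2.47 ± 0.66, adjusted p = 0.013; 0.154 without replicate 1, 0.0618 without replicate 2 and 0.0625 without replicate 3). In proliferating cultures MKI67 rose by 2.12 ± 0.27, AREG from 46.9 ± 8.86 to 401 ± 85 CPM (3.09 ± 0.27) and SESN2, a stress-induced p53 target, by 1.94 ± 0.37. NR1H4, which encodes FXR, fell there from 124 ± 22.8 to 5.95 ± 4.61 CPM (-4.35 ± 0.34) and CYP2C8 from 410 ± 139 to 22.8 ± 19 CPM (-4.16 ± 0.50). The cell cycle list was higher in differentiated cultures (21 up and 0 down of 33 probes, 27 and 0 adjusted over the list alone; adjusted p = 0.0448 with an estimated correlation) and the PXR and CAR list lower in proliferating cultures (0 and 13 of 18; 0.0358). In differentiated cultures the PXR and CAR list was not called (2 and 0 of 20; adjusted p = 0.757), and in proliferating cultures the cell cycle list (24 and 0 of 34) had 4.52e-13, which was 0.0869 with an estimated correlation. In proliferating cultures the p53 list (15 and 0 of 25) had an adjusted p of 1.83e-08, which was 0.0703 with an estimated correlation.

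Ritonavir lowered hepatocyte genes and raised single genes of the integrated stress response, among them enzymes of amino acid supply, though the list of that response was not called with an estimated correlation. In differentiated cultures PHGDH, the first enzyme of serine synthesis, went from 22.5 ± 0.652 to 203 ± 46.7 CPM (3.17 ± 0.30 on the log2 scale, n = 3), and WARS, which charges the tryptophan tRNA, rose by 3.14 ± 0.35 (adjusted p = 2.4e-07). TRIB3, a regulator induced by ATF4, went from 288 ± 45.3 to 1912 ± 849 CPM (2.73 ± 0.22), and PSAT1 rose by 2.70 ± 0.25. NR1I3, which encodes CAR, fell from 32.3 ± 2.79 to 0.826 ± 0.694 CPM (-5.26 ± 0.57). In proliferating cultures (n = 2) PSAT1 rose by 2.76 ± 0.52 and TRIB3 by 2.61 ± 0.51, and FABP1, a lipid carrier of liver, fell from 856 ± 85.2 to 5.3 ± 0.701 CPM (-7.34 ± 0.52). The unfolded protein response list had 12 up and 0 down of 19 probes in differentiated and 4 and 0 in proliferating cultures (adjusted p = 4.4e-10 and 1.5e-05, 0.106 and 0.134 with an estimated correlation). The hepatocyte list was lower in both (0 and 11 of 16 in each; 0.0448 and 0.00112 with an estimated correlation), and the FXR list in differentiated cultures (0 and 5 of 6; 0.000669).

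In differentiated cultures the calls of HSPA6 and of ATF3, a transcription factor of the stress response, with CPZ rested on a single run. The treated sums of replicates 1, 2 and 3 held 4843, 8 and 11 counts of HSPA6 among 1340560, 5116561 and 9938356, and 597, 22 and 59 counts of ATF3. HSPA6 went from 0.468 ± 0.351 to 996 ± 1723 CPM over the 3 runs (adjusted p = 0.011), and it rose by 2.22 on the log2 scale without replicate 1 (adjusted p = 0.386), with an adjusted p of 0.128 without replicate 2 and 0.0768 without replicate 3. In proliferating cultures (n = 2) HSPA6 had 6 counts among 78019 and 30 among 1857277, a rise of 5.31 on the log2 scale that edgeR did not call (adjusted p = 0.132, 0.0332 with the block and 0.00108 with DESeq2). ALB fell there from 9591 ± 1099 to 399 ± 181 CPM (-4.62 ± 0.62, adjusted p = 0.00038). The hepatocyte list was lower there, with 0 up and 7 down of 16 probes (adjusted p = 2.72e-09, 0.134 with an estimated correlation), and the unfolded protein response list higher in differentiated cultures, with 6 and 0 of 19 (1.25e-06, 0.269).

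Other compounds changed few probes or none at the index concentration. Tamoxifen, an oestrogen receptor drug, raised FABP4 in proliferating cultures from 64.5 ± 4.71 to 382 ± 90.8 CPM (n = 2; 2.56 ± 0.39 on the log2 scale, adjusted p = 0.012). CDCA, a bile acid, raised PEG10, an imprinted gene, by 1.01 ± 0.14 in proliferating cultures (adjusted p = 0.00034; 0.0646 without replicate 1 and 0.11 without replicate 3). PPBP, a platelet chemokine, rose with FFA by 1.21 ± 0.20 (adjusted p = 0.0041; 0.371 without replicate 2 and 0.535 without replicate 3) and with caffeine by 0.74 ± 0.14 (adjusted p = 0.022; 1 without replicate 1, 1 without replicate 2 and 0.272 without replicate 3) in differentiated cultures. FPR1 (0.77 ± 0.16) and AKR1B10 (-0.81 ± 0.16), each with an adjusted p of 0.035, were the 2 calls with sucrose, and neither held without replicate 1 (1 for both), 2 (0.113 for both) or 3 (0.592 and 0.695).

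In differentiated cultures edgeR called 0 probes for 9 compounds, with the number at an unadjusted p under 0.05 and the number by DESeq2 as follows. These were 65 and 0 for aspirin, 43 and 1 for CDCA, 42 and 0 for cyclophosphamide, 46 and 1 for KCl, 84 and 3 for diphenhydramine, 31 and 0 for DMN, 24 and 0 for tamoxifen, 89 and 0 for levofloxacin and 51 and 6 for VPA. In proliferating cultures edgeR called 0 probes for 10 compounds: 50 unadjusted and 3 by DESeq2 for aspirin, 61 and 1 for cyclophosphamide, 30 and 0 for KCl, 8 and 0 for DMN, and 14 and 0 for sucrose. There were 25 and 0 for caffeine, 31 and 4 for FFA, 17 and 0 for levofloxacin, 45 and 0 for PB and 29 and 0 for VPA. With the block, edgeR called 85 for levofloxacin, 67 for VPA, 29 for KCl, 17 for aspirin and 13 for diphenhydramine in differentiated cultures, and 23 for aspirin, 23 for cyclophosphamide and 11 for FFA in proliferating cultures. Without the block edgeR called no probe for aspirin at any concentration in either state, and none for cyclophosphamide in differentiated cultures. With it the highest count was 196 for aspirin in differentiated (at 0.09487 µM) and 77 in proliferating cultures, and 148 for cyclophosphamide in differentiated cultures. The PPAR list was higher with FFA in proliferating cultures (0 up and 0 down of 13 probes, 7 and 0 adjusted over the list alone; adjusted p = 0.000432 with an estimated correlation).

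Over the 24 compounds in differentiated cultures, 90 of 343 pairs of compound and list were called, 43 higher and 47 lower, and in proliferating cultures 83 of 345, 42 higher and 41 lower. With an estimated correlation 17 and 20 were called, all among those. With the block the numbers were 106 and 98.

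A test of the difference between states asked which compounds acted differently in differentiated and proliferating cultures. B[a]P lowered the liver-secreted HP in proliferating cultures. It changed HP by -0.41 in differentiated cultures, which edgeR did not call (adjusted p = 0.260), and by -8.46 in proliferating cultures on the log2 scale. The difference was 8.07 ± 0.66 (SE, adjusted p = 6.9e-14, n = 3 runs per group). PCNA, the sliding clamp of DNA replication, moved in opposite directions with B[a]P, by -2.04 in differentiated (adjusted p = 0.0056, and 0.104 without replicate 3) and 2.58 in proliferating cultures, a difference of -4.61 ± 0.76 (adjusted p = 6.7e-06). APAP lowered CYP2C8 in proliferating cultures (-4.16) and not in differentiated cultures (0.38), a difference of 4.53 ± 0.84 (adjusted p = 0.00053, 0.12 without replicate 3). Ritonavir changed HP by -1.55 and -6.64 (5.03 ± 0.69, n = 2 in proliferating cultures), and RIF changed CYP3A5 by 4.37 and by 1.56, the second not called (2.80 ± 0.49, adjusted p = 0.0028; 1 without replicate 1 and 0.0529 without replicate 3).

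The difference between states was called for 2015 pairs of probe and compound over 12 compounds, 1173 with a positive and 842 with a negative difference, and for 3927 with the block. Menadione had 890, B[a]P 623, aflatoxin 400, APAP 53, trovafloxacin 29, ritonavir 12, troglitazone and CPZ 2 each, and rosiglitazone, RIF, tamoxifen and PB 1 each. For the other 12 compounds edgeR called 0, with 4 to 29 probes at an unadjusted p under 0.05 and 0 by DESeq2. DESeq2 called 1246 for menadione, 757 for B[a]P, 746 for aflatoxin, 103 for APAP, 67 for trovafloxacin, 48 for ritonavir, 37 for CPZ and 9 for troglitazone. With the block the counts were 1435, 1017, 673, 244, 308, 120, 16 and 64 in the same order, 24 for rosiglitazone and 14 for PB. The share of positive differences was 58.2% with TMM, 23.9% with RLE and 24.8% with DESeq2, so this split is set by the scaling. Without replicate 1 the count was 497 for menadione, 264 for aflatoxin, 29 for APAP, 19 for trovafloxacin and 79 for CPZ. Without replicate 2 it was 532 for menadione, 291 for B[a]P and 137 for aflatoxin, and the calls of trovafloxacin were lost. Without replicate 3 it was 574 for menadione, 91 for aflatoxin, 10 for APAP, 2 for trovafloxacin and 6 for CPZ. The calls of CPZ were lost without replicate 2, those of troglitazone without replicate 2 or 3, that of rosiglitazone without any of the 3, and those of RIF, tamoxifen and PB without replicate 1 or 3. Without replicate 1 or 3 menadione, CPZ, ritonavir, RIF and tamoxifen had a single proliferating run, so the differentiated groups alone gave the spread and these counts do not test the proliferating runs.

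Troglitazone was withdrawn for liver injury and rosiglitazone is the related drug, so their direct contrast at matched concentrations asked what sets them apart. Both carry a thiazolidinedione head, to which troglitazone joins a chromanol like that of vitamin E and rosiglitazone an aminopyridine. At 30 µM in proliferating cultures troglitazone left less of the liver-secreted HP than rosiglitazone, 130 ± 82 against 448 ± 92 CPM (SD, n = 3 each), and less of CYP4A22, a fatty acid oxidase, 8.27 ± 4.11 against 31.2 ± 7.97 CPM. COL3A1 was higher with troglitazone, 169 ± 15 against 82.5 ± 6.22 CPM. In differentiated cultures edgeR called 0 of 2611 probes (17 unadjusted, 0 by DESeq2, 2 with the block).

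In proliferating cultures 23 of 2584 probes differed, 2 higher and 21 lower with troglitazone. The log2 difference was -1.78 for HP (95% confidence interval -2.39 to -1.18; adjusted p = 0.0871 without replicate 1 and 0.164 without replicate 3), and -1.92 for CYP4A22 (-2.58 to -1.26; 0.142 without replicate 1). It was 1.04 for COL3A1 (0.49 to 1.58; 0.617 without replicate 1 and 0.683 without replicate 2) and -1.55 for CYP3A4 (-2.33 to -0.76; 0.892 without replicate 1, 0.185 without replicate 2 and 0.0517 without replicate 3). The count was 120 with the block, 43 with DESeq2, 10 with RLE, 14 without the filter and 2 when the groups of the contrast were fitted alone, and 1, 8 and 11 without replicates 1, 2 and 3. Of the hepatocyte list 0 were up and 8 down of 16 (0 and 13 adjusted over the list alone), and of the PXR and CAR list 0 and 5 of 19 (0 and 8). In differentiated cultures 59.7% of the intervals lay within 1 on either side of 0, with a median width on each side of 0.721, so larger differences were excluded for those probes and not for the rest. At 94.9 µM 17 probes differed in differentiated and 509 in proliferating cultures, and at 300 µM 1266 and 1440, where troglitazone left 0.400% and 0.224% of the DMSO counts.

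Trovafloxacin was restricted for liver injury and levofloxacin is its marketed relative. Trovafloxacin has a naphthyridone core with a difluorophenyl group and a bicyclic amine, levofloxacin a tricyclic quinolone core with a methylpiperazine. At 30 µM in differentiated cultures trovafloxacin gave more GDF15 than levofloxacin, 7103 ± 123 against 658 ± 422 CPM (SD, n = 3 each), more CYP1A1, 41.8 ± 15.7 against 3.08 ± 2.46 CPM, and more of the Notch target HES1, 457 ± 128 against 56.9 ± 7.43 CPM. It left less PPBP, 5.93 ± 1.33 against 180.2 ± 21 CPM. In proliferating cultures SPP1, a matrix protein of injured liver, was at 561 ± 53.1 CPM with trovafloxacin and 42.9 ± 6.30 CPM with levofloxacin. The log2 differences were 3.43 for GDF15 (95% confidence interval 2.27 to 4.60), 3.65 for CYP1A1 (2.32 to 4.98), 3.00 ± 0.22 for HES1 (SE, adjusted p = 1.8e-15), -4.91 ± 0.32 for PPBP and 3.71 for SPP1 (2.97 to 4.45).

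In differentiated cultures 760 of 2407 probes differed between trovafloxacin and levofloxacin at 30 µM, 352 higher and 408 lower with trovafloxacin, and in proliferating cultures 922 of 2581, 429 higher and 493 lower. With the block the counts were 1271 and 1227. Without replicate 2 the count in differentiated cultures was 504, and in proliferating cultures 599. At 3 µM 25 and 26 probes differed, and at 0.9487 µM 0 and 2 (5 and 4 with the block). Of the p53 list 13 probes were up and 2 down of 25 in differentiated (15 and 3 adjusted over the list alone) and 15 and 3 in proliferating cultures (16 and 3). Of the cell cycle list it was 14 and 0 of 33 (18 and 0) and 13 and 0 of 34 both ways, and of cholesterol synthesis 0 and 6 of 13 both ways and 1 and 7 (1 and 8).

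**Figure D5:**
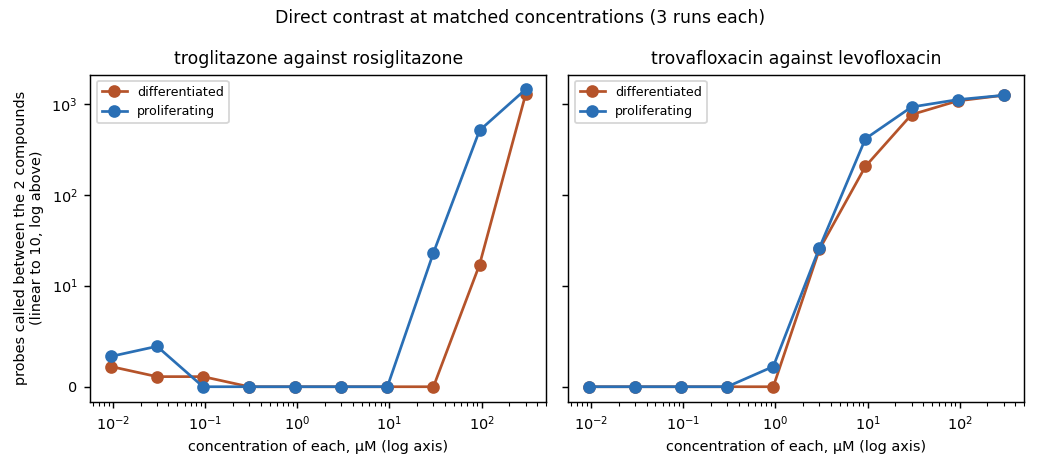
Probes called in the direct contrast of the compounds of each pair against their shared concentration (µM, log axis), the vertical axis linear to 10 and logarithmic above. At 30 µM troglitazone and rosiglitazone differed in 0 probes in differentiated and 23 in proliferating cultures, and trovafloxacin and levofloxacin in 760 and 922.

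The lowest active concentration, the lowest from which at least 10 probes were called at it and at every higher concentration, asked whether a culture state was more sensitive. It was lower in proliferating cultures for 7 compounds, lower in differentiated cultures for 2 and equal for 15, of which 7 were active in neither state. For B[a]P it was 0.949 µM in differentiated and 0.3 µM in proliferating cultures, for troglitazone 9.49 and 0.3 µM and for rosiglitazone 0.3 and 0.0949 µM. It was 30 and 9.49 µM for CPZ and 200 and 63.3 µM for CDCA, while it was 9.49 and 30 µM for menadione and 632.5 and 2000 µM for APAP. Levofloxacin and VPA were active in proliferating cultures alone, but with the block they were active in differentiated cultures from 0.03 and 0.0951 µM. A count of calls depends on power as well as on sensitivity, and power differed between states. In the simulated data 2-fold changes were recovered for 22.4% on differentiated and 71.6% on proliferating plate 1. On plate 2 it was 41.8% and 19.4%. The mean log10 ratio, proliferating to differentiated, over the 24 compounds was -0.146 ± 0.403 (SD), which did not differ from 0 (p = 0.0830 by a two-sided permutation test with 100000 resamples). With the block it was 1.33 (p = 0.00122), the opposite direction. In that fit KCl counted as active from 0.00948 µM and sucrose from 0.0949 µM in differentiated cultures. With the plate as a block, 63 probes also differed between the DMSO wells of columns 24 and 23 on differentiated plate 1. Well position may thus account for part of the calls with the block, so this value does not show that differentiated cultures were more sensitive. Without replicate 2 the mean log10 ratio was -0.292 (p = 0.00959). With at least 20 probes for an active concentration it was -0.0833 (p = 0.436), lower in proliferating cultures for 5 compounds and in differentiated cultures for 4. Over the 16 compounds that can be compared it was -0.219 with all runs (p = 0.0471), -0.125 without replicate 1 (p = 0.125) and -0.437 without replicate 3 (p = 0.0622).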

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

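The tests of KCl distance, of the depth of treated libraries and of all other splits of the samples were chosen only after the result was seen; a first form of the depth test and of the background test was replaced, the second before its value was seen.

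The difference between culture states was itself significant for at least 1 probe in 12 compounds, and this is what singled them out. There were 890 probes for menadione, 623 for B[a]P, 400 for aflatoxin, 53 for APAP, 29 for trovafloxacin, 12 for ritonavir, 2 each for troglitazone and CPZ, and 1 each for rosiglitazone, RIF, tamoxifen and PB. DESeq2 gave 1246, 757, 746, 103, 67, 48, 9 and 37 for the first 8 of these, and the block 1435, 1017, 673, 244, 308, 120, 64 and 16. Among named genes, the log2 change in differentiated minus that in proliferating cultures with B[a]P was 8.07 for HP and -4.61 for PCNA. With APAP it was 4.53 for CYP2C8 (adjusted p = 0.12 without replicate 3) and 3.94 for CYP3A4 (0.0666 without replicate 1 and 0.134 without replicate 3), and with ritonavir 5.03 for HP. With menadione it was 4.67 for CYP1A1, which in DMSO was higher in proliferating than in differentiated cultures. The menadione value rests on 2 proliferating runs at 1.23% of the DMSO counts. There RLE moved the median of all probes by 1.44 on the log2 scale, so its size depends on the scaling. With RIF it was 2.80 for CYP3A5 (1 without replicate 1 and 0.0529 without replicate 3) and with troglitazone 2.08 for FGG (0.0528 without replicate 2 and 0.282 without replicate 3). FABP4 moved apart with tamoxifen (-2.43, and 0.694 without replicate 1 and 1 without replicate 3) and with PB (-1.43, and 0.999 without replicate 1 and 1 without replicate 3). With trovafloxacin NDRG1 differed by -2.68 (0.465 without replicate 2) and ENO2 by -3.60 (0.124 without replicate 1, 0.991 without replicate 2 and 0.119 without replicate 3), and both genes were higher in differentiated than in proliferating cultures in DMSO. Without replicate 1 or 3 RIF and tamoxifen had a single proliferating run, so the differentiated groups alone gave the spread there.

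A well without a labelled compound held 11281075 counts, above the highest DMSO well at 4219306, and so did 62 of the 3976 such wells, 19 of them on plate 4. The wells of plate 4 had a median of 1229150.5 counts. The labels do not say what these wells held, so no explanation was tested. Depth of the DMSO wells per plate gave no plate beyond the critical gap in 8 tests; the closest was the lowest median DMSO well of a proliferating plate, with a gap of 0.525 of the range, just under the limit.

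CYP3A4 was already up at the lowest RIF concentration in differentiated cultures, by 3.18 (SE 0.426) in the test against other compounds and 3.20 in its own fit, and reached 6.32 at 92.02 µM. Material carried from neighbouring wells would have raised CYP3A4 in CPZ wells that lie between RIF columns as well, but their mean change over the 4 lowest concentrations was -0.592 (SE 0.531) while RIF changed it by 4.09 over the same. Position of the low-concentration columns would have raised it with sucrose and DMN in the same columns, where the mean change was -0.852 (SE 0.342). Carry-over of RIF within its own dilution series was not tested and stays open beside a real effect at 0.0092 µM, and the call at that concentration was lost without replicate 1 (adjusted p = 0.30) or 2 (0.505). In proliferating cultures CYP3A4 was at 0.75 at that concentration and not called.

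KCl gave 29 calls at its index concentration in differentiated cultures with the plate as a block and 0 by edgeR without it (46 at an unadjusted p under 0.05, 1 by DESeq2). DMSO wells of the edge column 24 differed from those of column 23 in 63 probes with the same block, so edge position may account for calls of this size, and calls with the block alone are read with this in mind. If distance between the KCl wells and the DMSO columns were the cause, the lowest concentration, which stood next to the DMSO columns, would have given fewer calls than the index concentration, but it gave 94. A real effect of KCl stays open: against its own lowest concentration the index concentration gave 4 calls with the block.

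Aflatoxin in both states (1405 and 1565 probes) and menadione in proliferating cultures (774) were called on sums that held 4.94%, 0.528% and 1.23% of the DMSO counts. Counting error at low depth alone did not give such counts: KCl and sucrose sums thinned to the same depth gave 0 calls by edgeR (54, 183 and 54 at an unadjusted p under 0.05 in these cases). DESeq2 was not run there. Thinning a deep sum adds counting error only, so any further spread of such small libraries was not tested. Whether a constant number of background counts per well lay behind the rises of rare probes could not be told. Probes under 1 CPM in DMSO held on average 0.980 times the DMSO counts per well in treated wells (SE 0.174, 8 runs), but the runs differed: the ratio was 1.80, 1.41 and 1.39 in replicate 1 of the 3 cases and 0.533 to 0.95 in the others. The mean lay in the range from 0.5 to 1.5 that had been set before, but that each run must lie in it was asked only after the values were seen. Total counts had fallen further in all of them, so the share of these probes rose from 0.0186% to 0.601%, from 0.0232% to 4.86% and from 0.0199% to 2.07%. Rises of probes that are rare in DMSO may come from background or from the cells, and falls of abundant probes and a loss of RNA from dying cells stay open as biology.

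Splits of the same samples into other groups of the same sizes number 10 for 3 runs against 3, too few for a share under 0.05. The real split gave the most calls by edgeR for the culture state (412, and 0 for the highest other split), the compounds in differentiated (4542 and 10) and in proliferating cultures (4826 over 16 compounds and 0), and the interaction (1109 over 16 compounds and 118, in a split that keeps a replicate number together). It also did for the pairs troglitazone and rosiglitazone in proliferating cultures (23 and 2) and trovafloxacin and levofloxacin in both (760 and 22, 922 and 1). In each of these 1 of 10 splits reached the real count, the real one. For troglitazone and rosiglitazone in differentiated cultures the real split gave 0 by edgeR (17 at an unadjusted p under 0.05, 0 by DESeq2), which all 10 reached. List calls did not stand apart: the real split gave 90 in differentiated cultures and the highest other 86, in a split that parts all replicate numbers, and in proliferating cultures 54 over 16 compounds against 57, with 2 of 10 splits as high. List calls in many splits point to a structure of the samples that the preset correlation does not carry; with an estimated correlation the real splits gave 17 and 10 and the highest other 0.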

How the results depend on the processing

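Leaving out compounds with low depth, leaving out PB and APAP, and the alternatives of the list test between culture states were chosen only after the data were seen.

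The replicate number as a block raised counts: 948 for the culture state (412 without), 8686 and 9270 for the compounds in differentiated and proliferating cultures (4542 and 5737), 3927 for the interaction (2015), 2 and 120 for troglitazone against rosiglitazone in differentiated and proliferating cultures (0 and 23), and 1271 for trovafloxacin against levofloxacin in differentiated cultures (760). The block reversed the mean log10 ratio of lowest active concentrations, from -0.146 to 1.33, with KCl counted as active from 0.00948 µM in differentiated cultures. For single genes and lists it changed 9 list calls and 1 named gene, HSPA6 with CPZ in proliferating cultures. Plates as samples gave 971 for the culture state. The cause of these changes was not tested beyond the correlation of runs that share a number.

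Leaving out each replicate gave 79 to 428 for the culture state, 2538 to 3882 for compounds in differentiated cultures, 1009 to 1362 for the interaction, 1 to 11 for troglitazone against rosiglitazone in proliferating cultures, 504 to 704 and 599 to 929 for trovafloxacin against levofloxacin in differentiated and proliferating cultures, and -0.437 to -0.125 for the lowest active concentration. Fewer runs were tested in each. With replicates 1 and 3 alone for plate 2 the lowest active ratio was -0.188 (p = 0.0414).

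An estimated correlation left 17 list calls of 90 in differentiated and 20 of 83 in proliferating cultures. Troglitazone against rosiglitazone in proliferating cultures gave 43 with DESeq2, 10 with RLE, 14 without the filter and 2 when the groups of the contrast were fitted alone; the cause was not tested. Without compounds of low depth the totals were 3398 in proliferating cultures and 725 for the interaction, over 22 compounds each, since aflatoxin and menadione had held the rest.

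A single gene and a single list reversed. ADIPOQ with rosiglitazone in differentiated cultures was at -0.085 when the lowest concentration was the reference. Its rise was thus no larger at the index concentration than at the lowest, where PLIN2 was called against DMSO. The hepatocyte list with KCl in differentiated cultures had an adjusted p from 1.36e-12 to 0.905 with each replicate left out, the last in the opposite direction and without replicate 1. The cause was not tested. Of 2017 values of 191 named genes 1845 kept their direction and call, 169 lost and 2 gained the call, and of 1076 values of 189 list results 831 kept both, 240 lost and 4 gained the call. Of 517 counts per compound 365 stayed within 1.5 times, as did 195 of 270 counts of the interaction.

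With wells of low counts left out no sum remained for aflatoxin in either state or for menadione in proliferating cultures, so their values could not be computed. Leaving out replicate 1 or 3 left a single run and no residual degrees of freedom for the compounds of plate 2 in proliferating cultures in their own fits, and in the interaction the differentiated groups alone gave their spread. Depth limits what can be said where sums held under 10% of the DMSO counts: a probe at 0 counts there has only a bound.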

Other observations

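The lowest concentrations held fewer counts than DMSO: the sums of the lowest concentration of a compound had between 36.5% and 87.9% of the DMSO counts per well in differentiated cultures. They stood in the columns next to DMSO, so concentration and plate column cannot be told apart. By column the median there ran from 36.7% of the DMSO counts in column 22 to 158% in column 9. No explanation was tested.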
